A study of Mus musculus with 32 samples.

How the data were processed

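Olfactory mucosa of adult S100a5-tauGFP mice was dissociated and sorted by fluorescence into GFP-positive and GFP-negative cells after exposure to vehicle, eugenol or muscone, per the labels. Per the labels' protocols, mice spent 26 h in clean air and then 14 h with pulses of 10 s every 5 min. Total RNA of the sorted cells was labelled as biotinylated cRNA and hybridised to 32 Affymetrix arrays, per the labels. The arrays form 8 groups of 4: vehicle or odorant, GFP-positive or GFP-negative, in eugenol and in muscone experiments. Each odorant had its own vehicle arrays.

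The deposited values are log2 intensities of 35,556 probe sets, and per the submitters' processing notes they were made in Affymetrix Expression Console. Its version, the background correction, the normalization and the summary method are not given in the sources used here. The values ran from 1.80 to 14.95 (log2) with 0 missing. The median of all probe sets differed between arrays, from 6.72 to 8.81. A number of 32 arrays, 4 per group, limits the precision of every value.

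The platform annotation gave exactly 1 gene symbol for 21,789 probe sets and several for 1621, of which 100 included an odorant receptor. Another 12,146 had no annotation. Names were checked against the RefSeq gene table of assembly GRCm38.p6, where 21,698 probe sets with 1 symbol matched by gene ID and 0 symbols needed an update. That table served for names and for which genes neighbour each other. Probe sets with 1 symbol were tested, and the probe set with the highest mean over the 32 arrays stood for a gene that had several. This left 19,938 genes, 1026 of them odorant receptors. The remaining probe sets were fitted apart.

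Groups were compared with limma 3.58.1 in R 4.3.3. All 32 arrays entered 1 fit with 8 group means and the experiment as a fixed block, which made 14 coefficients and 18 residual degrees of freedom. The prior added 3.71 degrees of freedom to give 21.7. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene passed at an adjusted p under 0.05. Every adjusted p given for a gene is limma's. Odorant receptors were also adjusted over the list alone. For each odorant the comparisons were odorant against vehicle in GFP-positive cells, the same in GFP-negative cells, and the change of the GFP-positive to GFP-negative difference, called reporter enrichment here. The others were GFP-positive against GFP-negative cells under vehicle and eugenol minus muscone effects in GFP-positive cells.

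The block comes from the array titles: 4 arrays, 1 of each stimulus and sorted fraction, share a number, and each set of 4 is called an experiment (eugenol 1 to 4, muscone 1 to 4). The pairing was checked by correlating each array's deviations from its group mean. For the 48 pairs of arrays from 1 experiment in different groups the correlation was 0.20 to 0.91 (median 0.66), and all 48 lay above 0.1. Between experiments of 1 odorant the median was −0.21 and the highest 0.44. With the block fitted, the p-values measure the spread between arrays that remains within experiments. The labels do not say whether the arrays of a group came from separate animals, so this is not taken as the spread between animals.

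Gene lists covered odorant, vomeronasal and trace amine-associated receptors (TAAR). Others held receptors linked to eugenol and to muscone, genes raised or lowered by olfactory neuron activity, and immediate early genes. Cell types listed were mature and immature olfactory neurons, basal progenitors, horizontal basal, sustentacular, microvillous, Bowman's gland, ensheathing glia, respiratory ciliated, immune, erythroid, endothelial, fibroblast and guanylyl cyclase D neurons. Further lists held dorsal and ventral zone, unfolded protein response, oxidative and xenobiotic response, axon guidance, apoptosis, oxidative phosphorylation and sex-linked genes. The receptors linked to the odorants were written partly from recall of the study made on these samples, so their results are not independent evidence. Of 6 names in the muscone list 4 genes were measured, since Olfr1433 is an older symbol of Olfr1434 and Olfr1437 was not among the tested genes. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move 1 way on balance, were run beside it.

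Genes named in the text were chosen by a rule. It took genes past the threshold with 1 sign in all experiments of a comparison (the 15 largest changes per direction), and the 15 largest rises among odorant receptors. It also took up to 4 members of each list with the smallest p, and always S100a5, Omp and the members of the eugenol and muscone lists. Olfr871 was named through the odorant receptor list. The groups, tests, lists, this rule and the other ways of processing were fixed before the data were examined.

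The results were recomputed with quantile normalization and centring each array on the median of all probe sets, of the mature neuron list or of all odorant receptors. Other fits used a filter for genes above the array median on at least 4 arrays, array quality weights, a trended and robust prior, the mean of a gene's probe sets, and the 16 arrays of the odorant's own experiments. The fit was also run without the block, with an added correlation within the sorted pair, and without each experiment in turn. A fit without the muscone experiments 2 and 3 was added after seeing the data.

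The fit was tested on simulated data with independent normal noise at each gene's own spread, with 200 changed genes per comparison. At a log2 change of 1, the share of 67 changed genes recovered was 94.0% for eugenol in GFP-positive cells, 76.1% for eugenol reporter enrichment and 95.5% for eugenol in GFP-negative cells. For muscone the shares were 92.5%, 88.1% and 80.6% in the same order. They were 100% for the vehicle comparison and 85.1% for the difference between odorants. At a log2 change of 0.5 the shares of 67 genes were 58.2%, 35.8%, 58.2%, 53.7%, 28.4%, 62.7%, 83.6% and 22.4% in that order. Between 5 and 10 unchanged genes of 19,938 were called. The simulated noise was independent between genes, so this number does not cover shifts that many genes share on an array. With the block fitted, a regrouping of the real eugenol arrays between vehicle and odorant called 738 genes in GFP-positive cells. With 200 changed genes the adjusted threshold is easier to pass than where few genes change. These shares are therefore likely too high for a comparison in which only a few receptors respond. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.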

Results

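Transcripts were measured on 32 arrays from sorted cells of the olfactory mucosa of S100a5-tauGFP mice, whose GFP reports the expression of an activity-dependent gene of olfactory sensory neurons. Mice received vehicle or an odorant, either eugenol, the clove odorant, or muscone, a musk. Each odorant had 4 experiments, and each experiment gave 4 arrays: vehicle and odorant, each sorted into GFP-positive and GFP-negative cells. The median signal of all probe sets ran from 6.72 to 8.81 (log2) over the arrays, and arrays of 1 group correlated at 0.901 to 0.991 across the genes tested. The vomeronasal receptors, expressed mainly in another organ, had a median signal of 4.68 (3.46 to 5.72 over the arrays), which describes the dim end of the scale. All differences are on the log2 scale, with the standard error (SE) of the fit. Counts of genes with a raw p under 0.05 in limma are given beside the calls. Without any change a share of 0.05 of the genes would lie there. Among the odorant comparisons only muscone in GFP-negative cells and the difference between odorants in GFP-positive cells exceeded that share.

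The comparison of GFP-positive with GFP-negative cells under vehicle asked what the reporter gate held without added odorant. GFP-positive cells were richer in transcripts of mature olfactory neurons and poorer in those of progenitors, immature neurons, microvillous cells and blood cells. The first turned around with centring on odorant receptors, whose own median was higher still in GFP-positive cells. S100a5, the calcium-binding protein whose gene drives the reporter, was 0.43 higher (SE 0.15, higher in 8 of 8 experiments, adjusted p = 0.0171), but −0.22 when arrays were centred on the median odorant receptor. The mean S100a5 signal was 11.4 in eugenol experiment 1. In the other experiments it was 4.86 to 7.43, below the median of all probe sets on their arrays. Its adjusted p was 0.0630 without eugenol experiment 1 (+0.34), 0.0579 without muscone experiment 4 (+0.38) and 0.916 without the experiment block, which gave Omp the same p of 0.916, and ran from 0.00324 to 0.916 over all alternatives. The fit without the block leaves out the pairing of arrays, so differences between experiments count as spread in it. Omp, the olfactory marker protein of mature neurons, was 0.27 higher (SE 0.07, 8 of 8, adjusted p = 0.00114), but −0.13 with centring on mature neuron genes and −0.37 with centring on odorant receptors. Among 19,938 genes, 13,365 differed, 8990 higher and 4375 lower in GFP-positive cells. That split moved with the scaling, to 11,680 and 3668 after centring on all probe sets, 8496 and 4430 after quantile normalization, 948 and 9859 after centring on mature neuron genes, and 605 and 18,070 after centring on odorant receptors. The median of all genes was 0.14 higher as deposited, so a difference near that size marks a gene that moved with the bulk. A centring moves the difference of every gene by the same amount. A gene that turned around with it was therefore raised by less than the reference genes, and such turns are not separate results.

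Mature neuron genes were higher in 15 of 15 cases, with a median of 0.51, which turned to −0.13 with centring on odorant receptors, where 1 was higher and 6 lower. They included Pde1c, a phosphodiesterase of the cilia (+0.81), Slc17a6, a vesicular glutamate transporter (+0.63), and Cnga4, a subunit of the transduction channel (+0.63), of which Slc17a6 (−0.014) and Cnga4 (−0.017) turned around with centring on odorant receptors. Of 7 genes raised by neuronal activity 6 were higher and 0 lower (4 and 2, and 3 and 2, with centring on mature neuron genes and on odorant receptors), among them Lrrc3b, a leucine-rich repeat membrane protein (+1.10), Pcp4l1, a calmodulin-binding peptide relative (+1.06), and Kirrel2, an adhesion molecule of axons (+0.83). Kirrel2 lost its call with centring on odorant receptors (+0.18, adjusted p = 0.0753). Over the alternatives Lrrc3b and Pcp4l1 went down to +0.46 and +0.41. Of 3 genes lowered by activity, the semaphorin receptor Plxnc1 was lower (−2.03), while the ephrin Efna5 (+0.49) and the adhesion molecule Kirrel3 (+0.29) were higher. Both turned around with centring on odorant receptors (Efna5 −0.16, Kirrel3 −0.36), and Kirrel3 with centring on mature neuron genes too (−0.11). Immediate early genes, which respond within minutes to stimuli, were lower in 14 of 17 cases and higher in 0, including Btg2, an antiproliferative factor (−2.35), Fos (−1.66) and Junb (−1.50), both AP-1 subunits. Without the experiment block the adjusted p was 0.120 for Pde1c, 0.517 for Slc17a6, 0.331 for Cnga4, 0.0565 for Lrrc3b and 0.554 for Kirrel2, and over all alternatives the lowest and highest for these genes were 5.11e-13 and 0.841. Camera with the preset correlation called the mature neuron (adjusted p = 2.31e-04), activity-raised (0.0151) and immediate early lists (7.84e-08). With an estimated correlation these p-values were 0.420, 0.236 and 0.236.

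All 9 measured basal progenitor genes were lower in GFP-positive cells, with a median of −2.42. Neurod1, a proneural transcription factor, was lower (−3.75, SE 0.16, 8 of 8, adjusted p = 4.10e-14) and so was the proliferation marker Mki67 (−3.35). Of 11 immature neuron genes 8 were lower and 1 higher. Those lower included the transcription factor Nhlh1 (−3.16) and the growth cone protein Gap43 (−1.57). Of 8 microvillous genes 8 were lower, led by the cation channel Trpm5 (−3.69). All 13 immune genes were lower, including the B cell receptor component Cd79a (−3.59) and the antigen presentation chaperone Cd74 (−3.65). The largest falls were those of Chil3, a chitinase-like protein (−4.92, SE 0.25), Mmp8, a collagenase of neutrophils (−4.81), Rgs13, a regulator of G protein signalling (−4.70), and Ly6g, a neutrophil surface antigen (−4.69). Camera called the progenitor (adjusted p = 3.51e-10), immature neuron (1.53e-05), microvillous (1.39e-06) and immune (3.18e-10) lists, and the p-values with an estimated correlation were 0.0565, 0.115, 0.115 and 0.115. It called 10 lists in all with the preset correlation and 0 with an estimated one, while fry called 21.

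**Figure D1:**
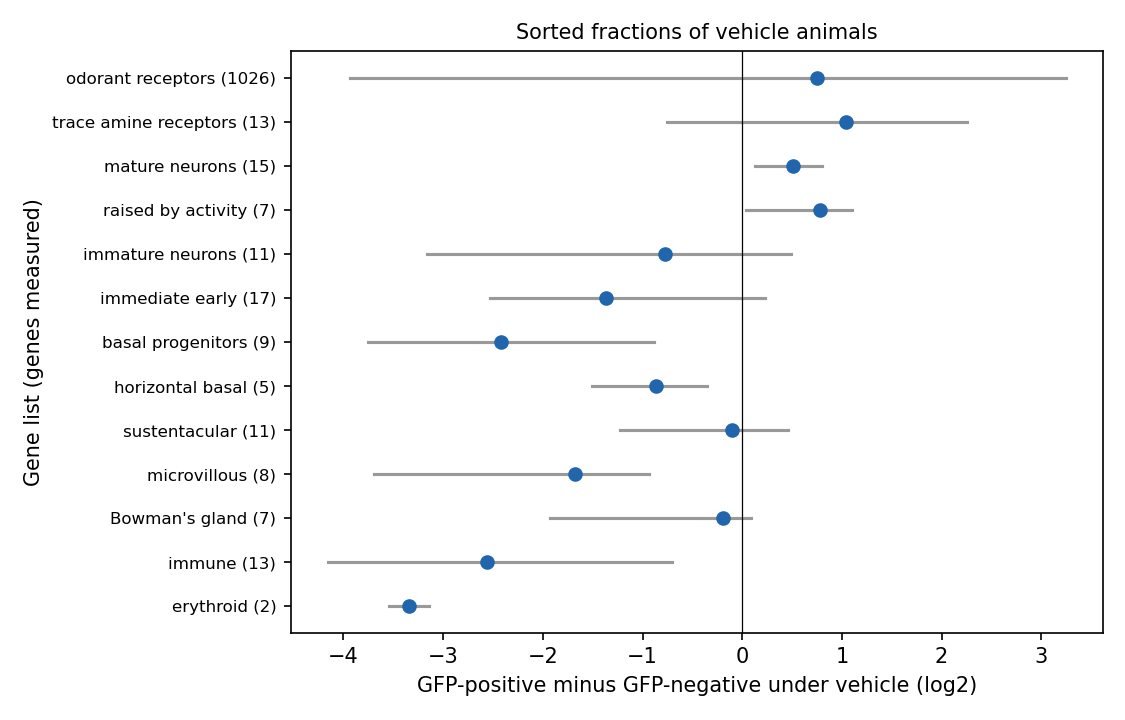
Difference between GFP-positive and GFP-negative cells under vehicle (log2, horizontal axis) for 13 gene lists, with the dot at the median of the list's genes and the line from the lowest to the highest gene. The mature neuron median lies at 0.51 (−0.13 with centring on odorant receptors), the odorant receptor median at 0.75 and the immune median at −2.56.

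Odorant receptors were spread to both sides of the gate. Of 1026, 672 were higher and 199 lower in GFP-positive cells, and 680 and 202 when adjusted over the list alone. With centring on mature neuron genes 509 were higher and 285 lower (522 and 290 over the list alone), and with centring on odorant receptors 439 and 364 (432 and 362). Their median was 0.75, or 0.35 with the first centring and 0.10 with the second, which holds it near 0 by construction. By more than 1, 409 were higher and 117 lower, or 232 and 162, and 154 and 197, with the centrings in the same order. Olfr472 was highest, 9.48-fold (+3.24, SE 0.17, 8 of 8, adjusted p = 7.06e-13), followed by Olfr490 (+2.88) and Olfr106-ps (+2.80). Olfr677 (−3.94) and Olfr77 (−3.65) were lower. Camera called the list (adjusted p = 1.89e-05), but the p was 0.361 with an estimated correlation. Among 13 trace amine-associated receptors 10 were higher and 2 lower (6 and 5 with centring on odorant receptors), with Taar9 (+2.25) and Taar4 (+2.12) as examples and a camera p of 0.0954.

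The genes linked to the 2 odorants already differed between the fractions under vehicle. Of the 6 eugenol receptors 5 were higher (3 with centring on odorant receptors), including Olfr958 (+1.62) and Olfr961 (+1.23), and Olfr74 was lower (−0.71; −0.61 with an adjusted p of 0.0642 without muscone experiment 4, and 5.49e-05 to 0.501 over all alternatives). Of the 4 muscone receptors Olfr1431 (+1.04) and Olfr235 (+0.61) were higher, Olfr1434 was lower (−2.33, SE 0.20, 8 of 8) and Olfr1440 did not pass (−0.10). The signal of Olfr1434 in GFP-positive cells (4.90 in the eugenol and 4.41 in the muscone experiments) lay at the dim level of the vomeronasal receptors, so the size of its difference is not taken as exact. Olfr1440 was called lower with centring on mature neuron genes (−0.50, adjusted p = 0.0127) and on odorant receptors (−0.75, 5.90e-04) and without muscone experiments 2 and 3 (−0.66, 4.28e-04), within 4.28e-04 to 0.999 over all alternatives. Olfr1431 lost its call without the block (0.186), with centring on odorant receptors (+0.39, 0.133) and without muscone experiments 2 and 3 (+0.51, 0.127), within 4.49e-04 to 0.186. The adjusted p of Olfr235 rose above 0.05 without any 1 of eugenol experiments 1 (+0.40, 0.0896) and 4 (+0.58, 0.0566) and muscone experiments 2 (+0.48, 0.0933) and 3 (+0.50, 0.0700), within 0.00381 to 0.876 over all alternatives. The same held without the block (0.655), with centring on mature neuron genes (+0.21, 0.318) and without muscone experiments 2 and 3 (+0.24, 0.421). Centring on odorant receptors turned Olfr235 to −0.033. These lists were written partly from recall of the study made on these samples and are not independent evidence.

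**Figure D2:**
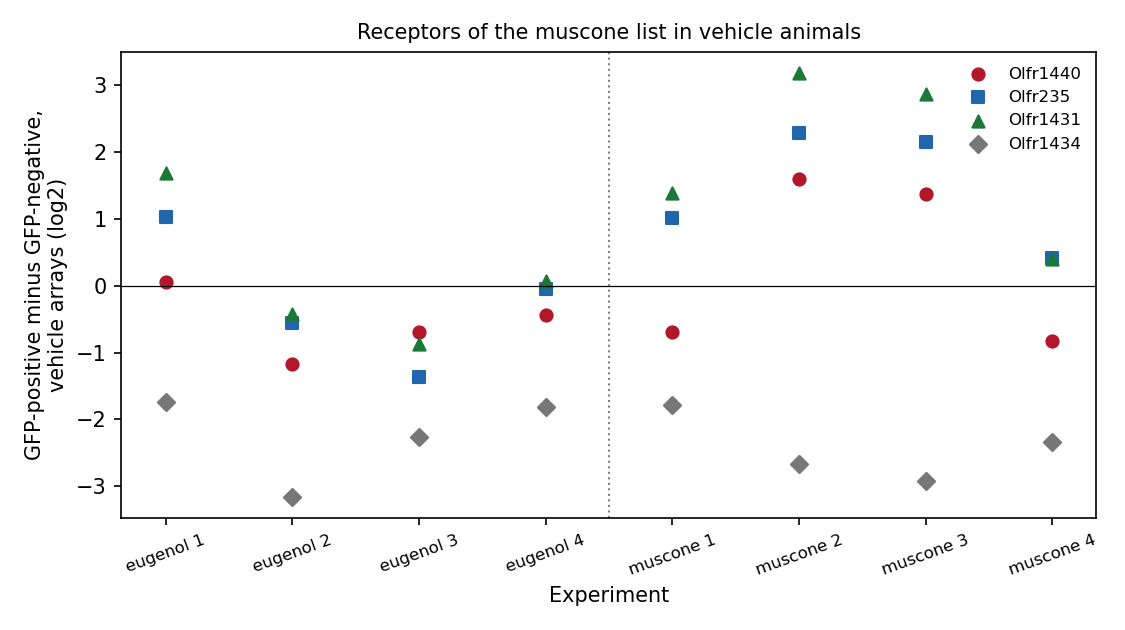
Difference between GFP-positive and GFP-negative cells under vehicle (log2, vertical axis) in each of 8 experiments (horizontal axis) for 4 receptors of the muscone list, with a point per array pair. Olfr1440 lies between −0.83 and 1.59 in the muscone experiments and between −1.17 and 0.05 in the eugenol experiments, and Olfr1434 lies below 0 in all 8.

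Muscone in GFP-positive cells addressed which receptors' transcripts became more abundant among reporter-positive neurons. A single gene of 19,938 passed, the odorant receptor Olfr1434, which rose by 2.38 (SE 0.29, 4 of 4 experiments, adjusted p = 7.86e-04). Its mean signal was 6.79 ± 0.30 (SD, n = 4) after muscone and 4.41 ± 0.83 (SD, n = 4) under vehicle, the latter at the dim level of the vomeronasal receptors, so the size of the rise is not taken as exact. A muscone receptor of brighter signal, Olfr1440, was 0.94 higher (SE 0.29, 4 of 4), but its adjusted p rounded to 1 over all genes and was 0.668 over the list alone. It reached 11.8 ± 0.55 after muscone and 10.8 ± 0.64 under vehicle (SD, n = 4). Olfr235 (+0.29, SE 0.31) and Olfr1431 (+0.19, SE 0.38) did not pass. In limma 746 genes had a raw p under 0.05.

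The muscone list thus held 1 receptor that rose, 0 that fell and 3 that did not pass, and it is not independent evidence because the study on these samples partly gave it. Of 1026 odorant receptors 1 rose, and 1 when adjusted over the list alone, where without muscone experiment 2 there was 1 that rose and 1 that fell. Camera called the muscone list (median 0.62, adjusted p = 2.91e-06), and the p with an estimated correlation was 0.0791. It also called immune genes (median 0.42, adjusted p = 2.50e-04) and oxidative phosphorylation genes (median −0.07, adjusted p = 0.0320), for which the p with an estimated correlation was 0.925 in both. The count for Olfr1434 fell to 0 without muscone experiment 2 (+2.24, adjusted p = 0.0963) and without the experiment block (adjusted p = 0.981). Its call was also lost without muscone experiments 2 and 3 (+1.85, adjusted p = 0.693), and over all alternatives its adjusted p ran from 9.39e-06 to 0.981.

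**Figure D3:**
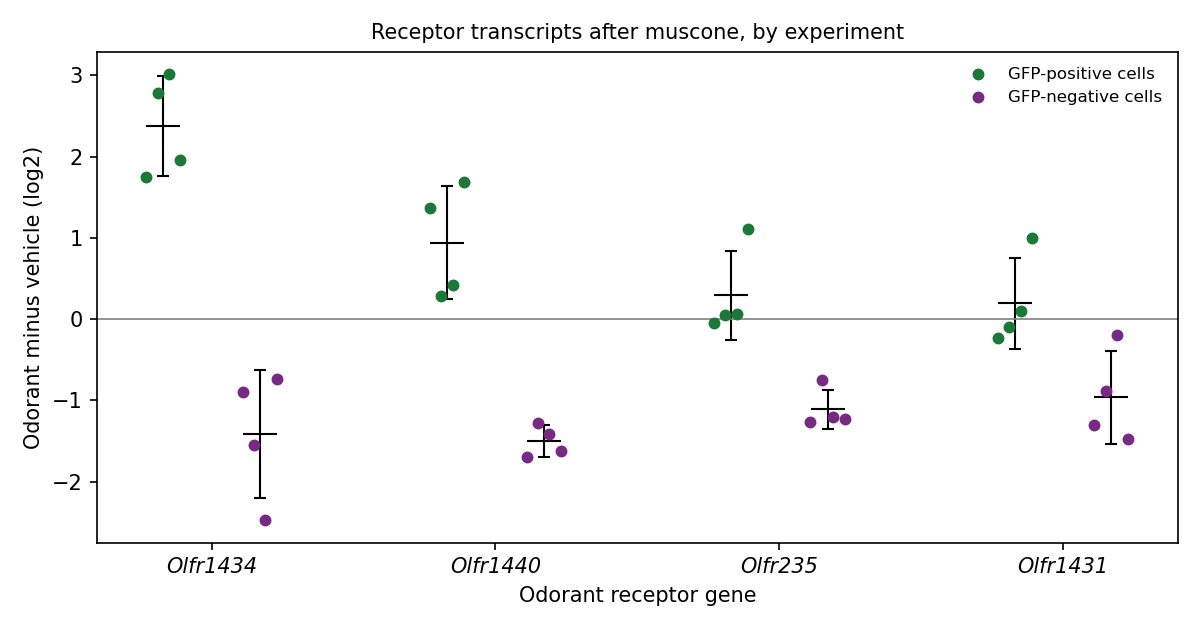
Muscone minus vehicle (log2, vertical axis) for 4 receptors of the muscone list, with a point for each of 4 experiments, green in GFP-positive and purple in GFP-negative cells, and the mean with the SD over experiments in black. Olfr1434 lies between 1.75 and 3.02 in GFP-positive cells and below 0 in GFP-negative cells.

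Reporter enrichment after muscone set the GFP-positive to GFP-negative difference against that under vehicle. Olfr1434 rose by 3.79 (SE 0.41, 4 of 4, adjusted p = 1.01e-04), with the same limit from the dim vehicle signal, and was again the single gene past the threshold, with 888 at a raw p under 0.05 in limma. Adjusted over the list alone, 3 odorant receptors rose: Olfr1434, Olfr1440 (+2.45, SE 0.41, 4 of 4, adjusted p = 0.00317) and Olfr871 (+0.70, SE 0.13, 4 of 4, adjusted p = 0.00498). The signal of Olfr871 was low, with means of 5.78 to 6.27 in the groups of the muscone experiments, and the filter for dim probe sets left it out. Over all genes Olfr1440 and Olfr871 had adjusted p-values of 0.0616 and 0.0967. Olfr1440 passed there in 6 of 16 alternatives and fell short in 10. Without muscone experiment 2 it passed (+2.74, adjusted p = 0.0425), which made 2 genes, and so it did with quantile normalization (+2.49, 0.0214). It also passed with centring on mature neuron genes (+2.36, 9.77e-04) and on odorant receptors (+2.17, 0.0233), and with array weights (+2.77, 0.00563). The last was the fit without muscone experiments 2 and 3, chosen after seeing the data (+3.19, 2.39e-04). Its adjusted p ran from 2.39e-04 to 1 over all alternatives. Olfr235 (+1.40, SE 0.44) and Olfr1431 (+1.16, SE 0.54) did not pass. The muscone list had 1 receptor that rose, 0 that fell and 3 not past the threshold (median 1.92, camera adjusted p = 8.28e-14, estimated-correlation p = 0.00224).

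Lists beyond the muscone receptors also passed camera in this comparison. The eugenol list had a median of 0.40 (adjusted p = 0.00323, estimated-correlation p = 0.0350), with 0 of 6 receptors past the threshold, and neither list is independent evidence. Endothelial genes had a median of −0.23 (adjusted p = 2.36e-04, estimated-correlation p = 0.0350), led by the growth factor receptor Flt1 (−0.54, SE 0.12). The odorant receptors as a whole had a median of 0.23 (adjusted p = 1.53e-16), and the p with an estimated correlation was 0.0546. Centring on odorant receptors holds this median near 0 by construction (−0.05), so it does not test this list. Immature neuron genes (median 0.18, adjusted p = 1.31e-04) and axon guidance genes (0.13, 9.85e-05) turned negative with that centring, and the p with an estimated correlation was 0.0993 and 0.0546. Trace amine-associated receptors (0.26, 0.0167) and mature neuron genes (0.09, 0.0169) also turned negative with it, and the p with an estimated correlation was 0.613 and 0.763. Olfr1434's call was lost without the block (adjusted p = 0.162) and without muscone experiments 2 and 3 (+2.67, adjusted p = 0.333), within 1.92e-06 to 0.333 over all alternatives.

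GFP-negative cells after muscone were compared to see whether cells outside the gate changed. With limma 0 genes passed, against 1704 with a raw p under 0.05. Adjusted over the list alone, 21 odorant receptors fell and 0 rose, among them Olfr1020 (−1.06, SE 0.20), Olfr1440 (−1.50, SE 0.29), Olfr1434 (−1.41, SE 0.29) and Olfr1022 (−0.65, SE 0.13), each lower in 4 of 4 experiments. Olfr1434 (5.42 after muscone) and Olfr1022 (4.63 after muscone, 5.28 under vehicle) lay within the range of the dim vomeronasal receptors, so the sizes of their falls are not taken as exact. The adjusted p-values of these 4 over the list alone were 0.0198, 0.0198, 0.0217 and 0.0217. Over all genes they were 0.153, 0.153, 0.153 and 0.169. The 21 became 0 without muscone experiment 1, 7 without experiment 3, 3 with centring on mature neuron genes and 0 with centring on odorant receptors. With the last, 10,126 genes passed, which eases the adjusted p of every gene. Over all genes Olfr1440 (−1.22), Olfr1434 (−1.13), Olfr1020 (−0.78), Olfr235 (−0.83) and Olfr1022 (−0.36) then passed as lower, with adjusted p-values of 0.00803 to 0.0259. As 0 receptors passed over the list alone, these passes are not read as calls that held. Olfr1440 also passed over all genes with centring on mature neuron genes (−1.35, adjusted p = 0.0351; 0.00788 to 1 over all alternatives), and Olfr1022 with quantile normalization (−0.68, 0.0198; 0.0157 to 1). As deposited, Olfr235 (−1.11, SE 0.31) and Olfr1431 (−0.96, SE 0.38) did not pass.

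The odorant receptors had a median of −0.25 in these cells (camera adjusted p = 1.74e-24, estimated-correlation p = 0.0259). It was +0.04 with centring on odorant receptors, which holds it near 0 by construction. The muscone list had a median of −1.26 (3.72e-08, estimated-correlation p = 0.0259) and the eugenol list one of −0.34 (0.00261, estimated-correlation p = 0.0259), medians that became −0.98 and −0.054 with that centring, with 0 receptors of either past the threshold over all genes, and neither is independent evidence. Endothelial genes had a median of 0.14 (4.36e-04, estimated-correlation p = 0.0367), led by Flt1 (+0.41, SE 0.08, 4 of 4, adjusted p = 0.153). Mature neuron (−0.14), immature neuron (−0.17) and axon guidance genes (−0.13) each had a camera adjusted p of 4.36e-04 and turned positive with centring on odorant receptors. Their p-values with an estimated correlation were 0.523, 0.155 and 0.0958. Trace amine-associated receptors had a median of −0.27 (8.73e-04), which became 0.02 with that centring, and the p with an estimated correlation was 0.345. Immune (0.33, 0.00502) and immediate early genes (0.17, 0.0166) were also called, and the p with an estimated correlation was 0.523 and 0.671.

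**Figure D4:**
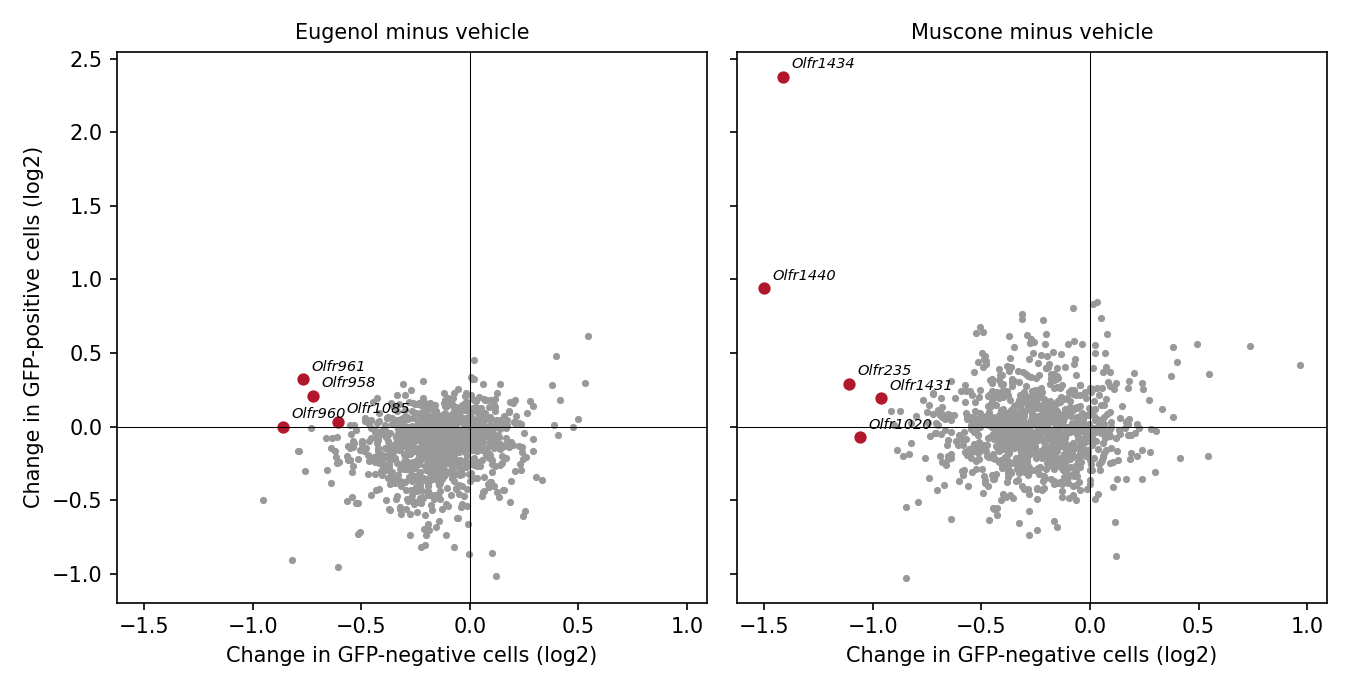
Change of each odorant receptor (dot) in GFP-negative cells (log2, horizontal axis) against that in GFP-positive cells (log2, vertical axis), for eugenol on the left and muscone on the right, with named receptors in red. Olfr1434 lies at −1.41 and 2.38 after muscone and Olfr961 at −0.77 and 0.32 after eugenol.

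Eugenol in GFP-positive cells addressed the same question for a second odorant. With limma 0 genes passed, against 923 with a raw p under 0.05, and 0 odorant receptors passed adjusted over the list alone. Olfr961 was 0.32 higher (SE 0.17, 4 of 4), at 10.6 ± 0.51 after eugenol against 10.3 ± 0.66 under vehicle (SD, n = 4). Olfr74 was 0.46 higher (SE 0.35, 3 of 4) and Olfr958 0.21 higher (SE 0.23, 4 of 4). Olfr73 (−0.20), Olfr912 (−0.25) and Olfr913 (+0.01) complete the eugenol list, whose median was 0.11 with a camera adjusted p of 0.473. Olfr1443 (−0.52, SE 0.14) was lower in 4 of 4 experiments without passing. Olfr834 (−0.55, SE 0.16, 4 of 4) did not pass either and lay at the dim level in both groups (4.38 against 4.93), so it is not read as a fall. Camera called sustentacular genes (median −0.65, adjusted p = 5.34e-04), immune genes (−0.44, 0.0302) and odorant receptors (−0.10, 0.0302), and the p with an estimated correlation was 0.955 for each. With centring on odorant receptors their own median was 0.06, held near 0 by construction. The number of lists called was 3 with all experiments, 0 without eugenol experiment 1, 6 without experiment 2 and 1 without experiment 4.

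Eugenol reporter enrichment was led by Olfr961, with a change of 1.09 (SE 0.24, 4 of 4), but with limma 0 genes passed and 237 had a raw p under 0.05. That is fewer than the share of 0.05 of all genes that would lie there without any change. The adjusted p of Olfr961 rounded to 1 over all genes and was 0.145 over the list alone, where 0 receptors passed. Olfr958 (+0.93, SE 0.32), Olfr960 (+0.86, SE 0.30) and Olfr1085 (+0.64, SE 0.19) were higher in 4 of 4 experiments. Olfr913 (+0.55), Olfr74 (+0.44), Olfr73 (+0.37) and Olfr912 (−0.14) are the other members of the eugenol list. None of the 6 receptors passed singly, but camera called the list (median 0.49, adjusted p = 7.81e-05, estimated-correlation p = 0.00657), which is not independent evidence.

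Lists of other cells were called for eugenol reporter enrichment with the preset correlation. They were sustentacular (median −0.81, adjusted p = 9.60e-08), basal progenitor (−0.48, 9.60e-08), immune (−0.54, 4.26e-04), immature neuron (−0.16, 0.0129) and Bowman's gland genes (−0.76, 0.0144). The p with an estimated correlation was 0.511, 0.0805, 0.599, 0.599 and 0.599 in that order. Among the Bowman's gland genes with the smallest p, Aqp5 (−0.41) was lower in 4 of 4 experiments and Muc5b (−0.83) in 3. Bpifb9a (−1.04) and Bpifb9b (−0.88) were lower in only 1 of 4, so a single experiment carried their change. Examples were Sox2, a transcription factor of supporting cells (−0.87, SE 0.44), the topoisomerase Top2a (−0.75, SE 0.24) and the leukocyte phosphatase Ptprc (−0.64, SE 0.39), none of which passed. Vomeronasal receptors had a median of 0.07 (adjusted p = 0.0202), which became −0.02 with centring on mature neuron genes, and the p with an estimated correlation was 0.889.

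**Figure D5:**
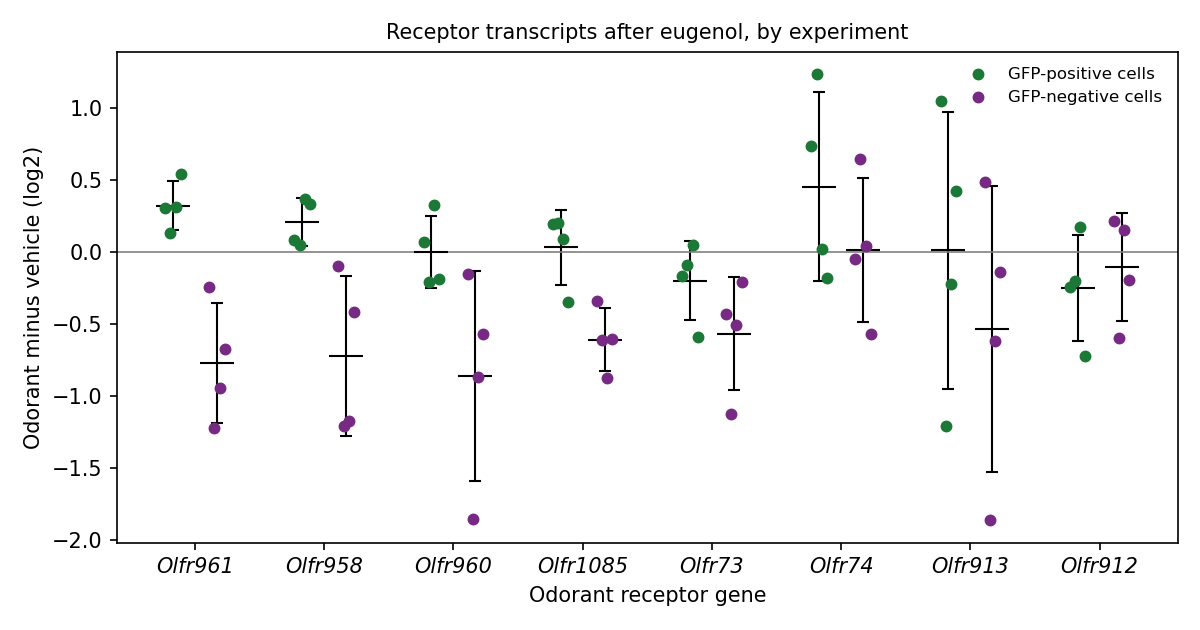
Eugenol minus vehicle (log2, vertical axis) for 8 odorant receptors, with a point for each of 4 experiments, green in GFP-positive and purple in GFP-negative cells, and the mean with the SD over experiments in black. Olfr961 and Olfr958 lie above 0 in GFP-positive and below 0 in GFP-negative cells in 4 of 4 experiments.

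GFP-negative cells after eugenol were compared on their own, a change that also enters the enrichment. Olfr961 (−0.77, SE 0.17), Olfr1085 (−0.61, SE 0.13), Olfr1512 (−0.66, SE 0.15), Olfr960 (−0.86, SE 0.21) and Olfr958 (−0.72, SE 0.23) were lower in 4 of 4 experiments. Over the alternatives Olfr1512 ran from −0.81 to −0.35 and Olfr960 from −1.10 to −0.53. With limma 0 genes passed, against 466 with a raw p under 0.05, and 0 receptors passed adjusted over the list alone, where Olfr961 and Olfr1085 each had an adjusted p of 0.0792 and Olfr1512 one of 0.0902. Olfr73 (−0.57), Olfr913 (−0.53), Olfr912 (−0.10) and Olfr74 (+0.02) are the remaining members of the eugenol list. The value of Olfr913 was unsteady and ran from −0.87 to −0.09 over the alternatives. The list passed camera with 0 of 6 receptors past the threshold (median −0.55, adjusted p = 1.44e-04, estimated-correlation p = 0.00727) and is not independent evidence.

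Further lists were called in GFP-negative cells after eugenol with the preset correlation. Odorant receptors (median −0.14, adjusted p = 0.00344), mature neuron genes (−0.14, 0.00876) and trace amine-associated receptors (−0.17, 0.0265) were on the lower side. Bowman's gland (0.44, 0.0199), basal progenitor (0.20, 5.52e-05), sustentacular (0.15, 0.0199) and immature neuron genes (0.07, 0.0253) were on the upper side. The p with an estimated correlation was 0.268 for basal progenitors and 0.902 for each of the others. The number of lists called was 8 with all experiments and 5 without eugenol experiment 2 or 3.

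The difference between the odorants was tested directly in GFP-positive cells. The effect of eugenol on Olfr1434 minus that of muscone was −2.90 as measured (SE 0.41, adjusted p = 0.00856), and it was the only gene of 19,938 past the threshold, with 1390 at a raw p under 0.05. Olfr1434 rose by 2.38 after muscone (4 of 4). The −0.52 after eugenol did not pass and sets 4.37 against 4.90 under vehicle, both at the dim level of the vomeronasal receptors, so it is not read as a fall although it enters the −2.90. With the vehicle signal of the muscone experiments (4.41) 3 of the 4 means behind that value are dim, and its size is not taken as exact. Its adjusted p was 0.0505 without eugenol experiment 1 (−2.97), 0.0972 without eugenol experiment 3 (−2.86) and 0.237 without muscone experiment 2 (−2.76) and 0.430 without muscone experiments 2 and 3 (−2.37), within 2.56e-04 to 1 over all alternatives. Olfr1440 differed by −1.20 (SE 0.41) without passing (adjusted p = 0.713). Camera called the muscone list (median −0.82, adjusted p = 5.47e-04), sustentacular (−0.92, 5.47e-04), immune (−0.95, 3.53e-04) and basal progenitor genes (−0.48, 0.00919). The p with an estimated correlation was 0.449 for the muscone list, which is not independent evidence, and 0.887 for each of the others. The lists called numbered 4 with all experiments and 7 without eugenol experiment 2.

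Tests added after seeing the data compared the odorants for reporter enrichment and in GFP-negative cells. For reporter enrichment Olfr1434 alone passed of all genes tested (−3.80, SE 0.58, adjusted p = 0.0273, dim signals included), with 528 at a raw p under 0.05. In GFP-negative cells limma called 0 genes, against 710 at a raw p under 0.05. Across 1026 odorant receptors, which are not independent replicates, the changes after the 2 odorants correlated at 0.00133 for enrichment, −0.09 in GFP-positive and 0.07 in GFP-negative cells, and these are 3 of 5 such correlations computed. Those between the fractions were 0.19 for eugenol and −0.00392 for muscone.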

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

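The tests of the muscone receptors under vehicle, of the eugenol receptors in GFP-negative cells and of an S100a5 allele were chosen after the result was seen, while those of the other splits of the samples and of S100a5 beside other activity genes were planned.

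Single experiments lay far from the other 3 for a few receptors. Olfr235 changed by 1.10 after muscone in GFP-positive cells of muscone experiment 4, against −0.05 to 0.06 in the others. In GFP-negative cells its change was −0.75 in muscone experiment 2, against −1.26 to −1.20. Reporter enrichment of Olfr1022 after muscone was 0.16 in experiment 3, against 0.85 to 0.97. Reporter enrichment of Olfr961 after eugenol was 0.55 in eugenol experiment 1, against 1.22 to 1.35. S100a8, a neutrophil protein, differed by −1.51 under vehicle in muscone experiment 3, against −4.96 to −3.89 in the other experiments. Acsm4, a ligase of dorsal zone neurons, differed by 1.29 in that experiment under vehicle, against 0.12 to 0.46. Reporter enrichment of Ptprc, a leukocyte phosphatase, after eugenol was −0.056 in eugenol experiment 1, against −0.85 to −0.79. Of 132 sets of values 7 held such an experiment, and chance alone gives about 1 in 20.

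The effect on Olfr1434 differed between the odorants, by −2.90 in the test of the difference itself, of which −0.52 is a difference after eugenol at the dim end of the scale, so its size is not taken as exact. Probe sets outside the gene table, 13,767 with several genes or no annotation, were fitted apart. Between GFP-positive and GFP-negative cells under vehicle 4076 of them passed, 899 of these naming several genes. In the other 7 comparisons limma called 0, with 169 to 674 at a raw p under 0.05.

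Other splits of the samples were fitted to see whether chance can be excluded. For the vehicle comparison chance can be excluded, since of 100 drawn ways to turn the fractions around within experiments 1, the real one, gave as many genes (13,365, highest other 11,536). Those high counts in other splits point to a structure of the samples, since a split that turns few experiments keeps most of the real difference. For muscone in GFP-positive cells and for its enrichment chance cannot be excluded. As many genes came from 5 of 35 splits in GFP-positive cells (real 1, highest other 15,407) and from 4 of 35 for reporter enrichment (real 1, highest other 57). The 15,407 came from a split that separates whole experiments, where the block could not be fitted, while the 57 came from a split with the block that parts 2 of the 4 pairs. Both point to a structure of the samples. Among the 8 splits that part all pairs the highest other was 0 in both comparisons, and 8 are too few for a share under 0.05. In GFP-negative cells after muscone and in the eugenol comparisons the real count was 0, which 35 of 35 splits must reach, so the splits say nothing about chance there. The highest other was 15,426 after muscone, again without the block, and 738, 0 and 148 for eugenol in GFP-positive cells, enrichment and GFP-negative cells, where high counts point to a structure of the samples. For the difference between odorants 2 of 35 gave as many (real 1, highest other 4), so chance cannot be excluded.

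The receptors of the muscone list were more enriched under vehicle in the muscone than in the eugenol experiments, by 1.07 on average. The labels give the vehicle animals of the 2 sets of experiments the same treatment, so no biological difference between them was tested, and the experiments overlap (exact two-sided permutation p = 0.143 over 70 splits). Against swapped vehicle and muscone arrays in muscone experiments 2 and 3, Olfr1434 rose there by 2.78 and 3.02, and against a shift of all receptors, the median receptor moved by 0.10. Whether muscone reached the vehicle animals stays open. The mean of the 4 listed receptors lay at percentile 100 of 10,000 random sets of 4 receptors, but that test came from the values that showed the pattern, on a list partly recalled from the study on these samples. Olfr1434 differed by −0.19, and the list means of muscone experiments 1 (−0.018) and 4 (−0.59) lay below that of eugenol experiment 1 (0.26). The differences of Olfr1440 (0.92), Olfr235 (1.70) and Olfr1431 (1.84) carried the pattern.

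After eugenol the median change of the 6 receptors of the eugenol list was −0.55 in GFP-negative cells (Olfr961 −0.77 to Olfr74 +0.02) and 0.11 in GFP-positive cells (Olfr912 −0.25 to Olfr74 +0.46), with 0 of 6 past the threshold in either. The list was written partly from recall of the study on these samples, so its percentiles among random sets are not independent evidence of the pattern. Relative to the median odorant receptor the list's median was still −0.42, at percentile 0 of 10,000 random sets, so as measured it fell beyond the median receptor. The members ran from −0.64 to 0.15 on that scale, so this does not hold for each of them. As the test was chosen after the pattern was seen, it does not decide against a lower share of all receptor neurons among the GFP-negative cells. A change common to both odorants cannot be told apart: muscone gave 0.612 of the eugenol median as deposited (−0.34) but 0.130 of it relative to the median receptor. The difference between the odorants lay at percentile 2.85 of random sets of 6 receptors. A move of responding neurons out of the GFP-negative gate with the odorant, which is the treatment of the design, stays open and was not tested.

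S100a5 was higher on the 4 arrays of eugenol experiment 1 (10.6 to 12.2) than on the other arrays (4.63 to 8.08), by 4.44 relative to the array medians. Higher neuronal activity in those animals is argued against, since the other 6 genes raised by activity differed by a median of −0.12 (−0.32 to 0.28). Another S100a5 allele may be the cause: S100a5 was the 1 gene that far from the other experiments, and the next gene differed by 2.90. That test came from the same values, and the labels give no genotype by experiment, so the allele stays open.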

How the results depend on the processing

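The alternatives were planned, except the fit without muscone experiments 2 and 3, which was chosen after seeing the data. In those experiments the mean difference of the muscone list between GFP-positive and GFP-negative cells under vehicle was highest (1.09 and 0.86). The pseudocount on the log scale was not run because the values were deposited as log2. A trended and robust prior, the mean of a gene's probe sets and an added correlation within the sorted pair left every count of genes and receptors within 1.5 times its value. Of the single gene values under alternatives 1946 kept direction and side of the threshold, 57 became weaker, 20 stronger, 9 without a call moved, and 22 reversed, all from higher to lower under vehicle with a centring. Since a centring moves every gene by the same amount, any gene raised by less than that amount had to reverse. The 22 are therefore not separate failures of single genes. Olfr1434 was dim under vehicle (4.41), so its fold is limited by signal over background. Except where fewer genes or arrays entered, the cause of a difference was not tested. Counts below are genes past the threshold, and receptors are adjusted over the list alone.

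The pairing of arrays entered through the replicate block, and without it 0 genes passed for muscone in GFP-positive cells, for muscone enrichment and between odorants, and 1668 (340 higher, 1328 lower) under vehicle. Receptors were then 0, 1 and 0 for muscone in GFP-positive cells, enrichment and GFP-negative cells, 567 (442 higher, 125 lower) under vehicle and 0 between odorants. Lists called were 12 and 11 for eugenol in GFP-positive cells and enrichment (3 and 7 with the block) and 5 for muscone in GFP-positive cells (3 with it). Of 118 single gene values 30 lost their call without the block, including S100a5, Omp, Pde1c and Kirrel2 under vehicle. In that fit the pairing is left out and differences between experiments count as spread, so it does not test the paired differences. The block moved no other count by more than 1.5 times.

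Quantile normalization gave 2 genes for muscone enrichment and 1 in GFP-negative cells, 1 receptor in each eugenol comparison, and 5 lists for eugenol in GFP-negative cells (8 as deposited). Centring on all probe sets gave 38 lower receptors in GFP-negative cells after muscone (21 as deposited). Centring on mature neuron genes gave 2 genes for muscone enrichment, and 2 genes and 3 receptors in GFP-negative cells after muscone. Under vehicle it gave Omp −0.13, Kirrel3 −0.11, Trib3 −0.016, Hrk −0.13, Cnga3 −0.13 and Npy −0.13. Centring on odorant receptors gave 13 genes for muscone enrichment and 1 receptor for eugenol enrichment. Under vehicle it gave S100a5 −0.22, Omp −0.37, Slc17a6 −0.014, Cnga4 −0.017, Efna5 −0.16, Kirrel3 −0.36, Olfr235 −0.033, Slit1 −0.088, Ndufb3 −0.15, Dnajb9 −0.21, Trib3 −0.26, Hrk −0.37, Nqo1 −0.10, Acsm4 −0.18, Cnga3 −0.37 and Npy −0.37. In GFP-negative cells after muscone it gave 10,126 genes (10,104 higher), since it takes the receptors' lower median for the level of the array. Adjusted over the list alone 0 receptors passed there, while Olfr1440, Olfr1434, Olfr1020, Olfr235 and Olfr1022 passed as lower over all genes (0.00803 to 0.0259). The 10,126 calls ease the adjusted p of every gene, so these passes are not read as calls that held. Leaving out dim probe sets removed Olfr1434 from the genes tested, which left 0 genes for muscone in GFP-positive cells, enrichment and between odorants, and 0, 1 and 0 receptors in the same order. Array weights gave 2 genes for muscone in GFP-positive cells and 2 for enrichment, with 1 and 2 receptors for eugenol enrichment and GFP-negative cells and 5 and 6 for muscone enrichment and GFP-negative cells. With the 16 arrays of the odorant's own experiments there was 1 receptor for eugenol in GFP-positive cells, and 1 and 3 for muscone enrichment and GFP-negative cells.

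Without muscone experiments 2 and 3 there were 6 genes and 6 receptors in GFP-negative cells after muscone, 2 receptors in GFP-positive cells, and 0 genes and 2 receptors between odorants. Olfr1440 in GFP-positive cells was then +1.53 with an adjusted p of 0.0405 (0.69 to 1.53, adjusted p 0.0405 to 1, over the alternatives), and Olfr1434 +1.85 with 0.693 (9.39e-06 to 0.981). For lists, an estimated correlation left 0, 1 and 1 for eugenol in GFP-positive cells, enrichment and GFP-negative cells, 0, 3 and 4 for muscone, and 0 for vehicle and between odorants. Fry gave 0, 1 and 1, then 0, 2 and 5, then 21 and 0 in that order.

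Without each experiment in turn, genes ran from 0 to 1 for muscone in GFP-positive cells (0 without muscone 2), 1 to 2 for enrichment (2 without muscone 2), 11,943 to 13,449 under vehicle and 0 to 1 between odorants (0 without eugenol 1, eugenol 3 or muscone 2). They stayed at 0 in the eugenol comparisons with limma, where raw p-values under 0.05 numbered 923, 237 and 466 with all experiments. Receptors ran from 1 to 2 for muscone in GFP-positive cells (2 without muscone 2) and 0 to 28 in GFP-negative cells (0 without muscone 1, 7 without muscone 3). Lists ran from 0 to 6 for eugenol in GFP-positive cells (0 without eugenol 1, 6 without eugenol 2, 1 without eugenol 4), 5 to 10 in GFP-negative cells (5 without eugenol 2 or 3), 2 to 4 for muscone in GFP-positive cells, 6 to 11 for enrichment and 3 to 7 between odorants (7 without eugenol 2).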

Other observations

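The test of neighbouring receptor genes was planned, while the correlations of receptor enrichment between experiments and the counts of receptors with 1 sign in all 8 were chosen after the result was seen.

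Axon guidance genes differed in both directions between the fractions under vehicle: 8 of 13 were higher and 2 lower in GFP-positive cells, with a median of 0.16 that became −0.24 with centring on mature neuron genes (2 higher, 7 lower). The ephrin receptor Epha5 (+1.11, SE 0.09) and the guidance ligand Slit1 (+0.56) were higher, and the semaphorin Sema3a was lower (−0.70). Oxidative phosphorylation genes were higher in 11 of 13 cases, including Ndufb3 of complex I (+0.50), with a median of 0.30 that turned to −0.10 and −0.34 with centring on mature neuron genes and on odorant receptors (0 higher with either, 2 and 12 lower). Camera called this list (adjusted p = 0.0184), and the p with an estimated correlation was 0.371. Of 9 oxidative and xenobiotic response genes 5 were higher and 1 lower, including Srxn1, which reduces peroxiredoxins (+0.87), and Gclc of glutathione synthesis (−0.54), against 1 higher and 7 lower with centring on odorant receptors. Of 14 unfolded protein response genes 5 were higher and 2 lower, including the chaperone Dnajb9 (+0.44), the pseudokinase Trib3 (+0.39) and the transcription factor Xbp1 (−0.36), but 0 were higher and 14 lower with centring on odorant receptors (Dnajb9 −0.21, Trib3 −0.26). Of 9 apoptosis genes 2 were higher and 4 lower, including Casp8 (−2.99), Bak1 (−1.01) and Hrk (+0.27), but 0 were higher with centring on mature neuron genes (Hrk −0.13) and on odorant receptors (Hrk −0.37, adjusted p = 2.64e-04). Slit1 (−0.088) and Ndufb3 (−0.15) also turned around with centring on odorant receptors. Without the experiment block the calls of Slit1, Sema3a, Ndufb3, Srxn1, Gclc, Dnajb9, Trib3, Xbp1 and Hrk were lost.

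Dorsal zone genes were higher in 2 of 2 cases, the quinone reductase Nqo1 (+0.54) and the ligase Acsm4 (+0.47), though their median of 0.51 became −0.14 with centring on odorant receptors. Of 2 ventral zone genes 1 was higher and 1 did not pass, with a median of 0.09 that became −0.31 with centring on mature neuron genes. In the list of guanylyl cyclase D neurons the phosphodiesterase Pde2a was lower (−2.77), the channel subunit Cnga3 higher (+0.27) and 2 genes did not pass. Cnga3 turned to −0.13 with centring on mature neuron genes and −0.37 with centring on odorant receptors (adjusted p = 1.92e-05), and lost its call without the block (0.916). Horizontal basal genes were lower in 4 of 5 cases, with Krt5 at −1.51, a camera adjusted p of 0.0149 and an estimated-correlation p of 0.252. Lower genes also numbered 2 of 11 for sustentacular cells (Sox2 −1.23), 2 of 7 for Bowman's gland (Sox9 −1.93), 3 of 5 for fibroblasts (Col1a2 −0.95) and 2 of 2 for erythroid cells (Slc4a1 −3.54, Alas2 −3.15). With centring on odorant receptors 8 sustentacular, 3 Bowman's gland and 5 fibroblast genes were lower. Endothelial genes were 1 higher and 2 lower of 5 (Pecam1 −1.15), ensheathing glia genes 2 higher and 0 lower of 6 (Npy +0.27), and respiratory ciliated genes 3 higher and 1 lower of 5 (Dynlrb2 +0.74). With centring on odorant receptors the endothelial genes were 0 higher and 5 lower, the glia genes 0 higher and 6 lower (Npy −0.37) and the ciliated ones 0 higher and 3 lower, and Npy was −0.13 with centring on mature neuron genes. Nqo1 (−0.10) and Acsm4 (−0.18) turned around with centring on odorant receptors. Without the block the calls of Nqo1, Acsm4, Npy, Dynlrb2 and Col1a2 were lost. Of 4 sex-linked genes 1 was higher and 1 lower (0 and 1 with centring on odorant receptors), and of 163 vomeronasal receptors 64 were higher and 1 lower (median 0.18, which became −0.23 with centring on mature neuron genes, where 0 were higher and 44 lower).

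Receptor enrichment under vehicle was alike between experiments. Across 1026 receptors, which are not independent replicates, it correlated at 0.731 to 0.926 over the 28 pairs of experiments. In all 8 experiments 561 receptors were higher and 144 lower, or 285 and 213 with centring on mature neuron genes and 288 and 272 with centring on odorant receptors.

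Neighbouring odorant receptor genes may share their enrichment under vehicle through their location or sequence similarity. Over 1009 adjacent pairs of the 1026 genes the enrichment correlated at 0.144 across genes, which are not independent replicates, against a highest value of 0.117 over 10,000 shuffled orders. Location and similarity of sequence, including shared hybridisation, cannot be separated by that value.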
